A study of Gallus gallus with 4 samples.

How the data were processed

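HIF-1α chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in the chorioallantoic membrane of 11-day chicken embryos, in 2 libraries from Chahua and 2 from Tibetan embryos. The breed of each library came from its labels and the replicate number from its title. No label says whether the libraries of a breed came from separate embryos or pools, so the p-values measure the spread between these libraries, which may be technical in part. No input or control library was among the samples used here.

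The submitters' processing notes name Bowtie2, MACS 1.4.2 and edgeR, without saying which step used which. The deposited files are named as peak lists, but each row held 1 aligned read with its chromosome, start, end, read name and a score. The score is the mapping quality per read, with a highest value of 60, as deposited by the authors. The files held no strand and no column of counts. The aligner settings and the genome build are not given in the sources used here. Chromosome names and highest coordinates were used as the files give them, and coordinates are printed counted from 1.

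Reads were joined to fragments by read name where both mates lay on 1 chromosome within 1000 bp, and a read without such a mate stood for its fragment. Fragments with a mapping quality under 10 were left out, and 1 fragment per start and end was kept. The joined share of fragments ran from 68.4% in Tibetan 2 to 76.4% in Chahua 1. Repeats of the same start and end made up 3.15% to 4.65% of fragments, and rows under the mapping quality minimum at most 0.0673%. The plan written before the data were examined had moved reads 100 bp towards their 3' end and had defined repeats by position and strand. Without strand, the fragment midpoint and the start and end took their place.

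Enriched regions were called within each library in 200 bp windows. A window passed with a Poisson p of at most 1e-05 against the larger of the autosomal mean and the mean of the surrounding 10 kb, and windows within 200 bp of each other were merged. Overlap was measured by the Jaccard index, the base pairs in both sets over the base pairs in either, for each of the 6 pairs of libraries and against 100 shuffles. Fragment density of a chromosome or segment is its fragments per bp over those of autosomes 1 to 28.

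Breeds were compared on fragments in autosomal regions called in at least 2 of the 4 libraries, with a mean of at least 20 fragments. The test was limma-voom with eBayes, two-sided, with Benjamini-Hochberg adjustment and a limit of 0.05 on the adjusted p. It takes the spread between libraries partly from all features tested, with 7.51 degrees of freedom for regions and 72.63 for the 10 kb bins below. The p-value of a bin thus rests mostly on spread pooled over bins. The library size was the number of autosomal fragments scaled by the median ratio over 10 kb bins. The counts were made here from the rows, so limma was used and no count model was fitted. The same test on all autosomal 10 kb bins was added after the data had been examined, as were the comparisons of Z, W and mitochondrial density and the rules for segments that 1 library lacked. Those rules were set after 3 bin sizes had been looked at. Single values were compared with two-sided exact permutation tests, for which the smallest p with 2 against 2 libraries is 0.333.

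The rule for naming regions took the 10 with the largest rise and the 10 with the largest fall in Tibetan against Chahua among those past the limit and with both libraries of 1 breed above both of the other. Where fewer passed in a direction, regions with the smallest p filled up to 5 and are said not to have passed. Segments and regions named because 1 library lacked them were chosen after their values were seen, as were the regions named for their density.

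Alternatives covered the library size, the minimum count, repeats, mapping quality, limma-trend, the replicate number as a block, the depth, the region set, the Poisson limit, the overlap rule, the Z chromosome, the sequencing run of Tibetan 1 and each library left out in turn. Read names placed Chahua 1 in lane 4, Chahua 2 in lane 7 and both Tibetan libraries in lane 3 of a single flow cell. In Tibetan 1, 22.4% of rows came from a second run on another instrument, with a median read length of 150 bases against 125 in the other rows. Lane and breed cannot be told apart in the first run, because no lane held both breeds.

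Both procedures were tested on simulated data. In 273462 simulated windows at a mean of 2.41 fragments, the caller found 48% of planted windows with 10 added fragments and 98.5% of those with 20. For the test of Tibetan against Chahua on 531 simulated regions with each region's own spread, limma called 4.48% of 1.5-fold changes, 37.3% of 2-fold changes and 63.6% of 4-fold changes. With 1 common spread for all regions it called 19.4%, 61.2% and 100%. With no change simulated, it called 0 of 531 with either spread. Among the 331 regions left unchanged beside changed ones it called 2 with each region's own spread and 3 with the common spread. On 90755 simulated 10 kb bins with each bin's own spread, it called 0% of 1.5-fold, 8.96% of 2-fold and 98.5% of 4-fold changes, and with 1 common spread 58.2%, 100% and 100%.

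Autosomal coverage by fragments was 2.79-fold in Chahua 1, 2.45-fold in Chahua 2, 2.47-fold in Tibetan 1 and 2.48-fold in Tibetan 2. A window at the autosomal mean therefore needed 13 fragments to pass. Where a count was 0, the limit given is that of 3 fragments and covers counting error only. No genome or annotation of the build was used here. Promoter reads, the fixed gene lists, the hypoxia response element motif and corrections for GC content were therefore not analysed here, and regions are named by position. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and numba 0.67.0, and R 4.3.3 with limma 3.58.1.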

Results

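HIF-1α, the oxygen-regulated subunit of a transcription factor that switches on genes when oxygen is low, was immunoprecipitated with its bound DNA from the chorioallantoic membrane, the vascular membrane through which the embryo exchanges gas across the shell. Tibetan chickens, a breed of high altitude, were set beside Chahua chickens, a lowland breed, with 2 libraries per breed at day 11 of incubation. The study asked where HIF-1α sits in the genome of Tibetan embryos and how this bears on life in thin air. Chahua 1 held 25706241 read rows, Chahua 2 held 23829463, Tibetan 1 held 21402335 and Tibetan 2 held 21035165. After joining and filtering, 13657014 ± 331917 fragments remained per Chahua library and 12079677 ± 11445 per Tibetan library (mean ± SD, n = 2). The ratio of Tibetan to Chahua was 0.885, with p = 0.333 in an exact permutation test, the smallest that this design allows. The median fragment was 223 bp in Chahua 1, 201 bp in Chahua 2, 229 bp in Tibetan 1 and 233 bp in Tibetan 2.

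On the sex chromosomes the libraries differed within breeds, and the breeds were also apart. Both Tibetan libraries lay below both Chahua libraries on Z and above both on W. In chickens, males carry a pair of Z chromosomes and females carry a Z and a W. Fragment density on Z, relative to the autosomes, was 0.971 in Chahua 1, 0.738 in Chahua 2, 0.690 in Tibetan 1 and 0.581 in Tibetan 2. On W the order was the opposite, at 0.0170 in Chahua 1, 0.297 in Chahua 2, 0.352 in Tibetan 1 and 0.441 in Tibetan 2. Only 294 fragments of Chahua 1 lay on W, against 5059 to 6867 in the other 3 libraries. The breed means on Z were 0.855 ± 0.165 for Chahua and 0.635 ± 0.0772 for Tibetan (SD, n = 2, exact permutation p = 0.333). The Tibetan mean minus the Chahua mean was -0.220 on Z and 0.240 on W. Without Chahua 1 these differences were -0.103 and 0.10, and without Chahua 2 they were -0.336 and 0.3796.

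The mitochondrial genome carried about the same density in both libraries of a breed and a higher one in Tibetan. Density relative to the autosomes was 10.9 and 12.5 in Chahua 1 and 2, and 23.1 and 22.3 in Tibetan 1 and 2. The means were 11.7 ± 1.13 for Chahua and 22.7 ± 0.625 for Tibetan (SD, n = 2), a ratio of 1.93. The exact permutation test gave p = 0.333, the smallest possible here. These densities rest on 2548 and 2876 fragments in Chahua and 4789 and 4655 in Tibetan. Both Tibetan libraries were denser than both Chahua libraries in 16 of 16 bins of 1 kb along the mitochondrial genome. Within Tibetan 1, the first run gave 22.8 and the second run, from another instrument, gave 24.6.

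**Figure D1:**
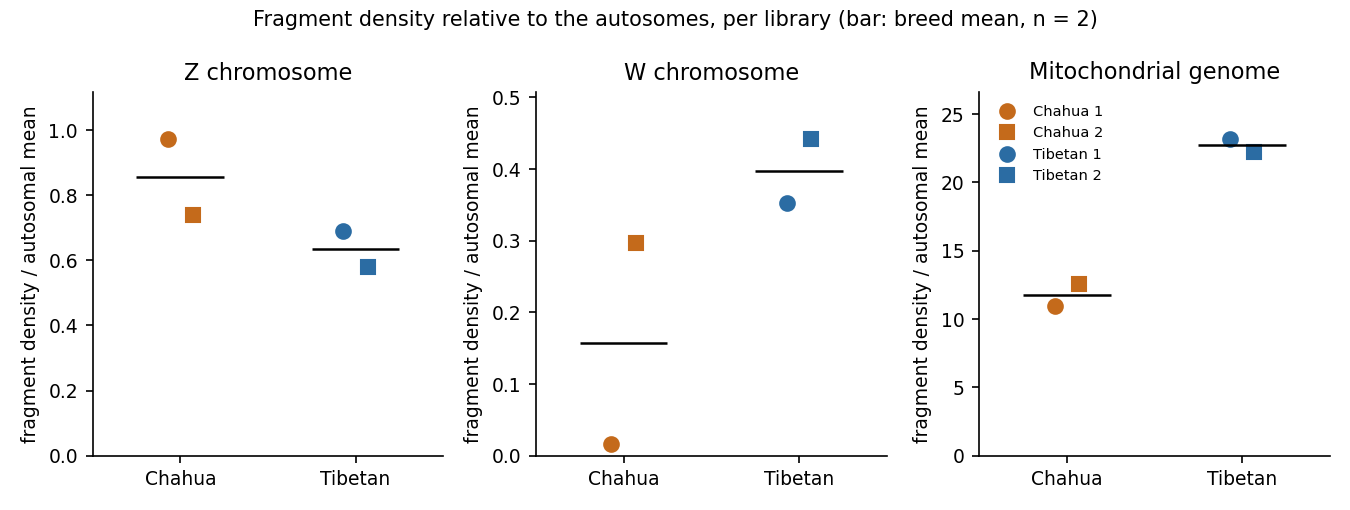
Fragment density relative to the autosomal mean on the Z chromosome, the W chromosome and the mitochondrial genome, with 1 point per library and a bar at each breed mean (n = 2). Chahua 1 stands at 0.971 on Z and 0.0170 on W, and both Tibetan libraries exceed 22 on the mitochondrial genome.

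A few autosomal stretches were nearly empty in Chahua 1, and the longest had a density close to that of the W chromosome. It lay on chromosome 1 from 160955001 to 161100000, where Chahua 1 had 27 fragments over 145 kb, Chahua 2 had 576, Tibetan 1 had 588 and Tibetan 2 had 829. Relative to the autosomes this was 0.0134, 0.291, 0.329 and 0.459, and relative to the W density of the same library it was 0.790, 0.980, 0.934 and 1.04, the value of Chahua 1 resting on its 27 fragments. On chromosome 2 from 84055001 to 84070000, Chahua 1 had 0 fragments, which allows at most 3, while the others had 150, 173 and 182. There the densities of 0.732, 0.935 and 0.973 were 2.21 to 2.66 times the W density. Of 6 shorter segments, 3 lay nearer to the W density in these 3 libraries, at 0.852 to 1.16 times on chromosome 2 from 53090001 to 53100000, and on chromosome 27 at 0.789 to 1.17 times from 55001 to 65000 and 0.765 to 0.818 times from 85001 to 95000. The other 3, on chromosome 1, ran from 1.02 to 5.53 times. Of 42 bins of 5 kb that 1 library lacked while the others did not, 39 were lacking in Chahua 1, 2 in Chahua 2, 0 in Tibetan 1 and 1 in Tibetan 2.

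**Figure D2:**
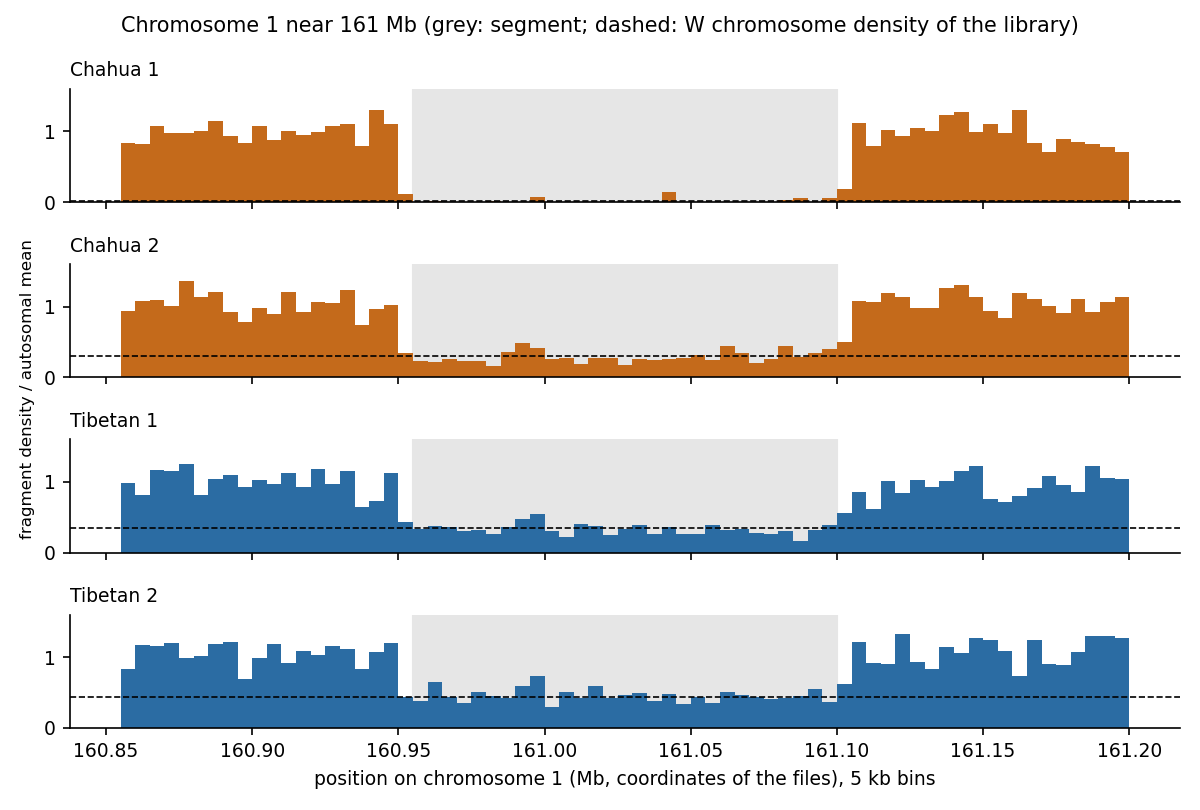
Fragment density relative to the autosomal mean in 5 kb bins along chromosome 1 around the segment from 160955001 to 161100000, with 1 panel per library. In the grey segment the density is 0.0134 in Chahua 1 and 0.291 to 0.459 in the others, close to the W density of each library (dashed line).

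Chromosome 16, the microchromosome that carries the major histocompatibility complex, was thinly covered in all 4 libraries. Its density was 0.611 in Chahua 1, 0.497 in Chahua 2, 0.472 in Tibetan 1 and 0.420 in Tibetan 2. Macrochromosomes 1 to 5 stood at 1.01 ± 0.00999 in Chahua and 1.01 ± 0.0126 in Tibetan, and microchromosomes 11 to 28 at 0.972 ± 0.0322 and 0.956 ± 0.0398 (SD, n = 2). These densities also varied with the sequencing run. Within Tibetan 1, chromosome 16 stood at 0.440 in the first run and 0.584 in the second, and microchromosomes 11 to 28 at 0.964 and 1.059.

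Enriched regions were few and strong at a small set of loci. The densest lay on chromosome 4 from 19202001 to 19202800, at 270.3 ± 9.26 times the autosomal mean (SD over 4 libraries). A second on chromosome 4, from 18720001 to 18720400, stood at 234 ± 36.5, and chromosome 8 from 9981601 to 9982200 at 138 ± 11.6. Chromosome 1 from 18025401 to 18026200 had a mean of 124.5 with a wide spread between libraries (± 118). Chromosome 2 from 52740001 to 52742600 reached 121 ± 12.2 and chromosome 7 from 7335801 to 7338400 reached 100.1 ± 27.02. These 6 regions were called in all 4 libraries. The share of their fragments at the highest mapping quality was 43.0%, 54.2%, 61.4%, 3.8%, 83.6% and 71.3% in that order, against a median of 93.9% over autosomal 10 kb bins.

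Regions whose fragments mostly had the highest mapping quality were rarer. Of the 670 autosomal regions called in at least 2 libraries, 41 (6.12%) had at least 90% of their fragments at the highest mapping quality, and 358 (53.4%) had under 50%. Of the 41, 12 were called in all 4 libraries. The densest of these 12 lay on chromosome 1 from 100377801 to 100378600, at 124 times the autosomal mean in Chahua 1, 88.0 in Chahua 2, 94.5 in Tibetan 1 and 49.5 in Tibetan 2. It was 1 of 22 regions in the Mb from 100 to 101 of that chromosome. The others there had from 0% to 87.6% of their fragments at the highest mapping quality. Chromosome 6 from 8789601 to 8790400 followed at 17.5 ± 3.15, chromosome 1 from 1833201 to 1834000 at 15.8 ± 7.01 and chromosome 20 from 5856801 to 5857000 at 12.8 ± 1.61 (SD over 4 libraries). Chromosome 20 also held a pair of such regions between 1760401 and 1763200, at 11.8 ± 3.42 and 12.6 ± 4.14.

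Regions clustered near chromosome ends and on microchromosomes. Stretches within 1 Mb of an end held 207 of the 670 regions (30.9%), or 3.8 per Mb against 0.729 per Mb over all autosomes. Microchromosomes 11 to 28 held 1.36 regions per Mb and macrochromosomes 1 to 5 held 0.602. The first Mb of chromosome 17 alone had 47 regions, and the first Mb of chromosome 27 had 26. Both stretches count as chromosome ends and as microchromosomes, so the densities of these classes are not separate results. On chromosome 1 the Mb from 100 to 101 had 22 and the Mb from 139 to 140 had 19.

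Chahua 1 had 870 autosomal regions, Chahua 2 had 747, Tibetan 1 had 683 and Tibetan 2 had 665, a mean of 808.5 ± 87.0 for Chahua and 674 ± 12.7 for Tibetan (SD, n = 2, exact permutation p = 0.333). With all libraries thinned to the same depth, the numbers were 750, 669, 683 and 652, so that Chahua 2 lay below Tibetan 1 (exact permutation p = 0.667). On Z, which was summarised apart, there were 143, 84, 57 and 33 regions in the same order. Windows on Z were also held to at least the autosomal mean, while Z density fell in this order (0.971, 0.738, 0.690 and 0.581). The numbers on Z therefore do not compare binding between libraries. Autosomal numbers cannot be read as binding alone either, because regions were called against the library's own mean without an input library. The autosomal regions covered 323.2, 278.2, 254.4 and 242.8 kb and held 0.702%, 0.599%, 0.607% and 0.523% of the autosomal fragments. Poisson counts alone would put 33.2 windows past the limit in Chahua 1, 28.2 in Chahua 2, 9.53 in Tibetan 1 and 10.7 in Tibetan 2.

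Each library shared between 50.1% and 68.4% of its regions with each other library, whatever the breed. Of the 683 regions of Tibetan 1, 64.4% overlapped a region of Tibetan 2, 66.9% one of Chahua 2 and 67.2% one of Chahua 1. The Jaccard index was 0.505 between the Chahua libraries and 0.518 between the Tibetan libraries. Across breeds it was 0.456 and 0.447 for Chahua 1 and 0.502 and 0.505 for Chahua 2. The mean within breeds was 0.511 and the mean across breeds 0.477. The difference of 0.0340 was the largest of the 3 ways to pair the libraries (exact p = 0.333, one-sided), and without Chahua 1 it was 0.0145, without Chahua 2 0.0665. Shuffled regions reached at most 0.00276 in 100 draws.

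**Figure D3:**
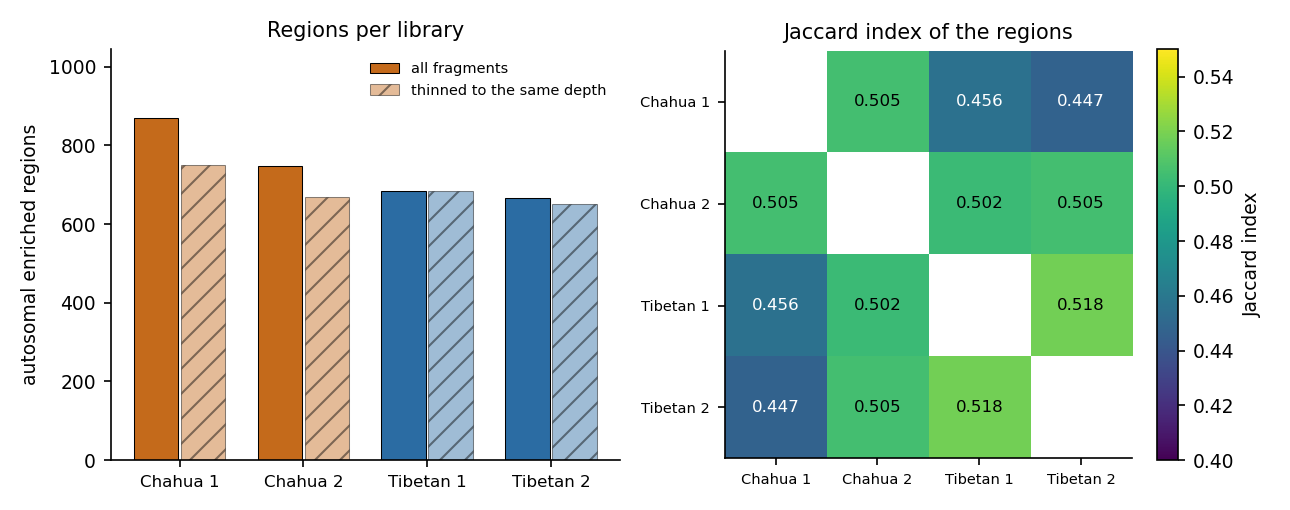
Number of autosomal enriched regions per library with all fragments and at the same depth (left, bars from 0) and Jaccard index of each pair of libraries (right, colour scale from 0.40 to 0.55). Counts run from 665 to 870, and the index from 0.447 to 0.518.

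Set breed against breed, no enriched region passed the test, and 1 locus stood apart. On chromosome 1 from 18025401 to 18026200, Chahua 1 had 518 fragments, Chahua 2 had 265, Tibetan 1 had 2790 and Tibetan 2 had 1440. The log2 fold of Tibetan over Chahua was 2.58 ± 0.44 (SE), with a limma adjusted p of 0.246, and 3.8% of its fragments had the highest mapping quality. The next smallest p-values among higher regions were at chromosome 11 from 2696001 to 2696200 (log2 fold 1.07 ± 0.27, but 0.17 with fragments at the highest mapping quality alone), chromosome 3 from 2404401 to 2405000 (1.06 ± 0.28), chromosome 1 from 113302801 to 113303600 (1.06 ± 0.30) and chromosome 25 from 18001 to 19000 (0.92 ± 0.33, with 0.52 without Chahua 1 and 1.31 without Chahua 2). None of these passed.

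Among regions lower in Tibetan, the smallest p-values were at chromosome 1 from 193410801 to 193411000, with 35 and 34 fragments in Chahua against 5 and 10 in Tibetan (log2 fold -2.05 ± 0.48). Chromosome 12 from 26401 to 27000 had 50 and 55 against 12 and 19 (-1.61 ± 0.41), and chromosome 1 from 115052601 to 115054200 had 213 and 154 against 82 and 78 (-1.03 ± 0.28). Chromosome 1 from 139324601 to 139324800 (-1.82 ± 0.53, with -2.41 without Tibetan 1 and -1.23 without Tibetan 2) and chromosome 27 from 750601 to 751200 (-1.25 ± 0.37) followed. The limma adjusted p was 0.597 for each of these 5, so that none passed.

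Over the 531 regions tested, 0 had a limma adjusted p under 0.05, and 33 had an unadjusted p under 0.05 where 26.6 are given by chance. With limma-trend the numbers were 0 and 34. Both libraries of 1 breed lay above both of the other in 38.2% of regions, where chance gives 33.3%. The region at 18 Mb of chromosome 1 passed in 4 alternatives with all 4 libraries, among them the 354 regions called in all 4 libraries (adjusted p = 3.66e-06) and fragments with a mapping quality of at least 30 (adjusted p = 0.0262). Over all alternatives its log2 fold ran from 2.10 to 3.35 and its adjusted p from 3.58e-07 to 0.833, and reached 0.833 without Chahua 1. The number of regions past the limit was 0 without Chahua 1, 7 without Chahua 2, 6 without Tibetan 1 and 8 without Tibetan 2.

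**Figure D4:**
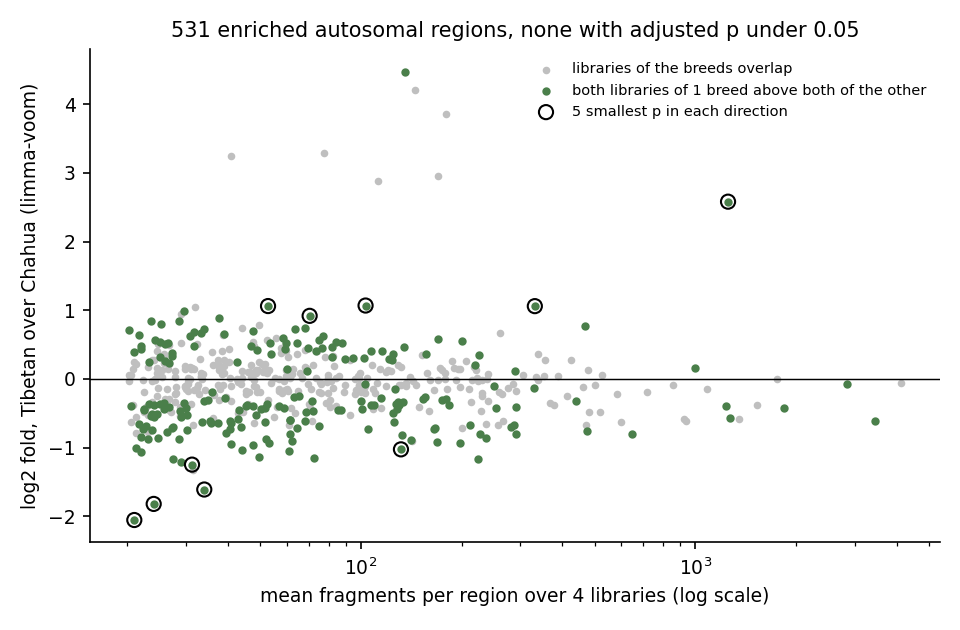
Log2 fold of Tibetan over Chahua against the mean fragments per region (log scale) for the 531 enriched autosomal regions tested, with the 5 smallest p-values in each direction circled. The circled region farthest above 0 is that at 18 Mb of chromosome 1, at 2.58, and 0 regions passed the adjusted limit.

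Some enriched regions were present in 3 libraries and nearly empty in Chahua 1. Of the 531 regions, 7 had at most 3 fragments in Chahua 1 and more than 15 in each of the others, while 0 regions were lacking in this way in Chahua 2, Tibetan 1 or Tibetan 2. They included chromosome 1 from 162852401 to 162852800 (0, 171, 170 and 202 fragments), chromosome 4 from 57138001 to 57138600 (1, 233, 196 and 291) and chromosome 2 from 27250201 to 27250800 (0, 226, 176 and 178). Between 4.7% and 23.9% of the fragments in the 7 regions had the highest mapping quality. Chahua 1 is also the library with almost no fragments on W. Its W density was 0.0170, against 0.297 in Chahua 2, 0.352 in Tibetan 1 and 0.441 in Tibetan 2. Whether these regions hold repeated W sequence, so that their lack follows the sex of the embryos, was not tested.

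Across autosomal 10 kb bins, a comparison added after the data had been examined, 12 bins were higher and 5 lower in Tibetan (limma, adjusted p under 0.05, 90755 bins tested). Of the 12 higher bins, 7 lay in the segment of chromosome 1 from 160955001 to 161100000 and 1 in that of chromosome 2 from 84055001 to 84070000. Chahua 1 had at most 1 fragment in each of these 8 bins, and their adjusted p ran from 0.00124 to 0.0325. Without Chahua 1 none of the 8 passed, with log2 folds of 0.31 to 0.91 and an adjusted p of 1 in each, so that these calls rest on that library. The bin of chromosome 1 from 18020001 to 18030000 held the region described above, at a log2 fold of 2.28 ± 0.32 (adjusted p = 4.96e-05). With fragments at the highest mapping quality alone, 9.7% of those in the bin, its log2 fold was 1.07 ± 0.18 (adjusted p = 0.00912, and 2.18e-22 to 0.99 over all alternatives). Chromosome 1 from 32560001 to 32570000 had 70 and 118 fragments in Chahua against 195 and 186 in Tibetan, a log2 fold of 1.22 ± 0.22 (adjusted p = 0.00481). The other 2 higher bins, outside the naming rule, were at chromosome 1 from 181740001 to 181750000 (0.77 ± 0.16) and chromosome 12 from 1190001 to 1200000 (0.92 ± 0.16).

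The lower bins were not among those that Chahua 1 lacked. Chromosome 16 from 300001 to 310000 had 59 and 75 fragments in Chahua and 4 and 8 in Tibetan, a log2 fold of -3.29 ± 0.55 (adjusted p = 0.00166). Chromosome 1 from 113130001 to 113140000 had 348 and 388 against 140 and 148 (-1.20 ± 0.18, adjusted p = 0.000313). Chromosome 9 from 2920001 to 2930000 (-1.15 ± 0.20), chromosome 13 from 80001 to 90000 (-1.02 ± 0.19) and chromosome 23 from 5630001 to 5640000 (-0.99 ± 0.17) also passed, with adjusted p between 0.0029 and 0.00525. In limma-trend the bin of chromosome 16 did not pass (-3.02, adjusted p = 0.446). With fragments at the highest mapping quality alone, that of chromosome 13 did not (-1.24, limma adjusted p = 0.256). The other lower bins passed in each of these settings. Over all 90755 bins, 3114 had an unadjusted p under 0.05 where chance gives 4538, and both libraries of 1 breed lay above both of the other in 31.6%, where chance gives 33.3%. The balance of directions depended on the setting, with 21 higher and 33 lower bins in limma-trend. Without Chahua 1, 10 bins were called (4 higher and 6 lower), 4 of them among the 17. Without Chahua 2, 39 were called, among them all 17, and without Tibetan 1 or Tibetan 2 the number was 0 (2365 and 1906 at an unadjusted p under 0.05).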

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

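All tests on the mitochondrial genome were chosen after its values were seen. The mitochondrial genome lies outside the autosomal comparison, and its density in Tibetan was 1.93 times that in Chahua. A lane effect in sequencing is argued against by the second run of Tibetan 1, made on another instrument, which gave a density of 24.55 and so stayed with the Tibetan value. Reads from nuclear copies that pile up locally are argued against because 100% of the 1 kb bins were denser in both Tibetan libraries. Sex is argued against as the main source, since the line through the Chahua libraries gives 13.8% of the breed difference, and Chahua 2 and Tibetan 1 had similar Z density but mitochondrial densities of 12.5 and 23.1. What stays open, as untested, is a breed difference in mitochondrial DNA per cell, and differences in tissue or chromatin preparation or in carry-over of unbound DNA, which no library here could separate from breed.

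A signal outside the enriched regions compared between breeds appeared in Tibetan 1 alone, on chromosome 8 from 8917001 to 8923000. The 10 kb bins that hold it were tested and neither passed (log2 folds of 1.09 ± 0.44 and 0.19 ± 0.30, limma adjusted p of 1 for both). Tibetan 1 had 466 fragments there, at 6.29 times the autosomal mean, against 0 in Chahua 1, 0 in Chahua 2 and 1 in Tibetan 2. With repeats removed within each run, the first run gave 338 and the second run 130, which share fragments of the same start and end, and 311 of the 466 had the highest mapping quality. The segment was found by a rule set after the bins had been looked at, and with 10 kb either side all libraries had fragments (1050, 1050, 1452 and 911 in Chahua 1, Chahua 2, Tibetan 1 and Tibetan 2).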

How the results depend on the processing

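Alternatives on 10 kb bins, on Z, W and mitochondrial density, on the runs of Tibetan 1, on joined pairs, on a mapping quality of 60 and on mapping quality for region numbers were chosen after seeing the data. Of 94 alternatives to the main results, 74 stayed within the spread or within 1.5 times the count, 20 moved and 0 reversed. For densities the spread was the SD within breeds, which is a wide limit on Z and W. Z differences of -0.103 without Chahua 1 and -0.336 without Chahua 2 thus both counted as having stayed. Over all rows the read ratio of Tibetan to Chahua was 0.857 in place of 0.885. Regions per library averaged 434 at a Poisson p of at most 1e-08 against 741.2, and their ratio of Tibetan to Chahua was 0.834, 0.727 with the genome mean alone and 0.941 at the same depth. The overlap difference ran from 0.0145 to 0.0665 with 1 library left out.

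Enriched regions that differed numbered 0, and 1 with the median ratio over the regions themselves, with a mapping quality of at least 30 and with regions called in all 4 libraries, each time the region at 18 Mb of chromosome 1. With 1 library left out they ran from 0 to 8, the lone library of a breed being assumed to vary like the others. The 17 bins of 10 kb became 9 at a mean of at least 50 fragments, 54 with limma-trend (21 higher and 33 lower, with 8 of the 17), and 0 with Tibetan 1 from its second run alone (6470 at an unadjusted p under 0.05 in limma). The first run thinned to the size of the second gave 21 (4 higher and 17 lower, with 5 of the 17). At that size bins were thus still called, but most of the 17 were lost, so the part of size in their loss stays open. With 1 library left out they ran from 0 to 39. Of 197 alternatives for the 10 named regions, 191 stayed on their side of the limit and 6 passed it. Of 172 for the 15 named bins, 89 stayed and 83 no longer passed. Beyond this, the cause was not tested.

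The replicate numbers share only a number. Deviations of same-numbered libraries correlated at 0.188 over regions and 0.202 over bins, with 2 pairs. With the replicate number as a block, 1 region and 93 bins (48 higher and 45 lower) were called, the latter including all 17.

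Promoter, gene list and motif alternatives, and those for GC content with or without the block, were not run.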

Other observations

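The tests in this part were chosen after the values were seen, except that on the sequencing lane, which had been planned for enriched regions and was applied to the 10 kb bins because no region passed.

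The segments that Chahua 1 lacked may have more than 1 origin. For chromosome 1 from 160955001 to 161100000, a candidate explanation is W sequence placed on chromosome 1 in the files' build: the density over the W density was between 0.934 and 1.04 in the other 3 libraries, the value of 0.934 being farthest from 1, and 0.790 in Chahua 1 on 27 fragments. The same explanation is argued against for the segment of chromosome 2 from 84055001 to 84070000, where the lowest density of the other 3 libraries was 0.732, above the 0.5 that a single copy in an all-female library would give, and more than 1 copy on W, or a deletion carried by the Chahua 1 embryos, stays open there. If Z and W densities measure the mix of sexes, Z would put the female share at 5.78%, 52.3%, 62.1% and 83.9% in Chahua 1, Chahua 2, Tibetan 1 and Tibetan 2, and W at 3.39%, 59.3%, 70.4% and 88.3%. Sex and breed then differ together, and the labels do not give the sex. The W share of Chahua 1 rests on a density of 0.0170, which was 0.00459 at a mapping quality of at least 30. In Chahua 2, Tibetan 1 and Tibetan 2 the W density at that limit was 0.277, 0.335 and 0.4195.

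A lane effect on Tibetan 1 was looked at in the 17 bins of 10 kb that differed between breeds. Its median signed log2 fold over Chahua in the second run was 1.03 times that in the first, with the same sign in 17 of 17 bins. In 8 of these bins Chahua 1 had at most 1 fragment, so the sign there was largely set whatever the run. Over the other 9 the medians were 1.16 in the first run and 1.22 in the second, with the same sign in 9. This argues against a lane effect on Tibetan 1 as the whole difference over these 9 as a set. The second run was part of the data that called the bins, and Tibetan 2 had no second run. For single bins a lane effect is not excluded: the second run gave 0.33 against 1.03 at chromosome 23 from 5630001 to 5640000, and on chromosome 1 0.67 against 1.42 from 113130001 to 113140000, 0.99 against 1.44 from 161030001 to 161040000 and 0.84 against 1.28 from 161050001 to 161060000. For sex, the median signed log2 of Chahua 2 over Chahua 1 was 0.769 over all 17 bins. Of these, 8 lie in segments found by their lack in Chahua 1. Over the other 9 it was 0.0194 (-0.76 to 0.769), with each bin below its breed difference. Bins that Chahua 1 lacked had been set aside, which favoured a small median. It therefore argues against sex only as the whole difference over the 9 as a set. At chromosome 1 from 32560001 to 32570000 sex is not argued against, with 0.769 of a log2 fold of 1.22. Without Chahua 1 the log2 fold there was 0.828. With fragments at the highest mapping quality alone, 16 bins kept 0.94 to 1.28 times their log2 fold (median 0.992), 11 of them passing and 5 with larger SEs not. In the 8 that Chahua 1 nearly lacked, the kept part was largely set whatever the filter, so nothing is concluded there. Over the rest as a set, reads shared between repeat copies that the build holds are argued against as the whole difference. The filter took out most at chromosomes 1 (from 113130001), 9 and 13. There 45.0%, 52.9% and 53.1% of fragments had the highest mapping quality, and 1.28, 1.06 and 1.21 times the log2 fold was kept. Reads from copies absent from the build can keep the highest mapping quality, so this comparison cannot decide on those. At chromosome 1 from 18020001 to 18030000 the log2 fold went from 2.28 ± 0.32 to 1.07 ± 0.18 and still passed, while that of the enriched region within it went from 2.58 to 3.35 without passing, so that the part of shared reads stays open there, and for all bins library preparation and a breed difference in binding or copy number stay open as untested.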
